A study of Drosophila melanogaster with 3 samples.

How the data were processed

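Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where BtbVII, a Drosophila protein with a BTB domain, sits on embryo chromatin. The flies carried BtbVII fused at its C terminus to enhanced GFP, and the immunoprecipitation used an antibody against GFP, per the labels. Chromatin came from whole embryos of both sexes aged 0 to 24 h and was sheared by sonication with a size range of 200 to 800, per the labels, which give no unit. The 3 libraries form 1 group and are numbered by the labels as biological replicates 1, 2 and 3. No control group was defined, so no comparison between groups of samples was made.

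The authors deposited region lists in narrowPeak format on 2 genome builds, dm6 and dm3. Each build has 5 lists: 1 for each replicate, 1 for the pooled replicates, and 1 list that passed an irreproducible discovery rate (IDR) threshold, called the optimal set. The replicate and pooled lists hold peaks and background intended as IDR input, and each holds exactly 30000 regions, so their length is a setting and not a result. Per the deposited README files, each list was derived from alignments that included, besides the replicates' own, a further alignment, which was taken to be the control. The aligner, the peak caller, their versions, the IDR threshold and any filter for duplicated or poorly mapped reads are not given in the sources used here.

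The value used to rank regions is the signal value that the authors' peak caller gave each region. Signal values were used only within a list, because their scale differs between lists: the highest is 1495 in replicate 1, 1554 in replicate 2 and 765 in replicate 3 on dm6. The deposited lists also hold a −log10 q-value, which runs from 2.61 to 3.83 in the optimal set and was not used to rank. The p column holds a placeholder throughout. All 5219 regions of the optimal set on dm6 were found in the pooled list, and they are exactly its 5219 regions of highest signal, with a minimum of 172.4. They are called strong peaks here, and the other 24781 pooled regions are candidates of lower signal. A comparison of strong peaks with the rest is therefore a comparison of higher with lower signal within 1 list. Of the strong peaks, 13 repeat the coordinates of another with a different summit, and each summit was counted.

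Read counts were not used here, so the depth of each library is unknown, and no interval below allows for it. Intervals on shares are exact (Clopper-Pearson) 95% intervals over peaks or genes and cover counting error only. Neighbouring peaks and genes are not independent, so p-values over them can be too small, and they do not measure the spread between collections of embryos. A multi-copy sequence may attract or lose signal through how its reads were placed, which cannot be checked from the lists.

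Positions were compared with the Release 6 genome sequence and with Ensembl release 115 gene models (BDGP6.54), whose chromosome lengths hold every dm6 region. Only dm6 coordinates are printed, counted from 1. The gene models on the chromosome arms held 18277 genes, 13968 of them protein-coding, and 35612 transcripts. A peak was placed by its summit. A summit within 500 bp of any annotated transcription start site (TSS) was called promoter-proximal, and the others were placed, in this order of priority, in coding exon, 5′ UTR, 3′ UTR, non-coding exon, intron or intergenic sequence.

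Replicates were compared by rank. From each replicate list the 5219 regions of highest signal were taken, to equal the number of strong peaks, and a strong peak was supported by a replicate when its summit lay in 1 of them. Pairs of replicates were compared by the share of these regions overlapping by at least 1 bp, averaged over both directions, against 100 random placements within chromosomes. Spearman correlations of signal over shared regions describe regions, which are not independent replicates.

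The background for location, chromosome and sequence tests was the 21880 candidates of lower signal more than 500 bp from any strong peak, and 2901 closer candidates were left out. Each test was a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over its family, and 0.05 was the threshold on the adjusted p. For gene lists, a gene was near a strong peak when a summit lay within 1000 bp of any of its TSSs, and the background was the protein-coding genes with any pooled candidate summit in that window. A total of 25 gene lists and 17 motifs was fixed before the data were examined, and lists with fewer than 5 genes in the background were not tested. Symbols were matched to current ones, and 2 list entries found no protein-coding gene. The eggshell and yolk list took in Cp190, which is not an eggshell gene, by its symbol, and the list of gut, fat body and trachea regulators includes brm, a chromatin remodelling gene. Another 11 gene lists were chosen after the data were seen and are reported among the other observations.

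For sequence tests, the 100 bp on each side of the summit were searched on both strands. Each strong peak was paired with 1 background region of the same class (promoter-proximal or not) and the same 2-point bin of GC content, drawn with seed 20240; 5214 peaks found a partner and 5 did not. All 2080 distinct 6-mers were tested beside the fixed motifs. Sequences that pass are not independent, since overlapping 6-mers are counted in the same windows. After the data were seen, the draw of partners was repeated 100 times with other seeds for motifs and the 2 6-mers of lowest p, and 20 times for all 6-mers. Intervals on ratios of site density came from 1000 bootstrap draws over regions.

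Named items followed a rule fixed before the data were examined: the 20 strong peaks of highest signal supported in all 3 replicates, with the gene of the nearest TSS; the 4 members with the highest-signal peak in each gene list past the threshold; BtbVII, Trl, psq and any Hox gene with a strong peak within 1000 bp; every fixed motif; and the 5 6-mers of lowest p in each direction. 1 item that this rule selects is not reported here. Other genes named as examples of a group were chosen after their values were seen.

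The tests were tried on data with known answers. A gene list near strong peaks at 80% against 42% for the other genes was called in 100 of 100 simulations over 7413 genes, with a mean of 0.04 of the 22 other lists called. These rates are close to the shares observed for ribosomal protein genes and other genes. For 6-mers, windows of weaker candidates were split at random into sets of 5000. All 20 planted 6-mers were called when placed in a further 6% of windows, and 46 others, not planted themselves, were called after it. None of the 2080 was called without planting. A random split does not show how many false calls a comparison of strong with weaker regions makes.

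Alternatives fixed before the data were examined were the dm3 lists, the upper part of the signal ranking, support in all replicates, leaving out each replicate, other numbers of top regions, other overlap rules, other windows, other backgrounds and no matching. One alternative, a single TSS per gene, was added after the data were seen. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.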

Results

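The binding of GFP-tagged BtbVII was mapped in 3 biological replicates of whole Drosophila embryos aged 0 to 24 h. The question the design poses is where this BTB-domain protein lies on embryo chromatin and which of those regions recur between replicates. The optimal set held 5219 strong peaks on dm6, with 945 on 2L, 1034 on 2R, 1146 on 3L, 1234 on 3R, 844 on X and 16 on chromosome 4. The optimal set on dm3 held 4373. The depth of the libraries is unknown.

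The strongest recurrent peak lay in an intron of CG11050 (2L, 6612426 to 6612926), 1019 bp downstream of the nearest TSS, with a signal of 3724. It ranked 1 in replicate 1, 1 in replicate 2 and 3 in replicate 3. The next, at 480872 to 481301 on 2L, had its nearest TSS at cbt, 1369 bp away, but its summit lay in an intron of ush, which encodes a zinc finger cofactor of GATA factors. A peak 44 bp upstream of Ugalt, a UDP-galactose transporter gene (X, 2703676 to 2704079), had a signal of 3686 and ranked 3, 2 and 2. The fourth was in an intron of Trl (3L, 14759310 to 14759751), the gene for GAGA factor, another BTB protein that binds GA-rich DNA, with a signal of 3114 and ranks of 4, 5 and 4. A second strong peak lay in the 5′ UTR of Trl, 125 bp from a TSS (3L, 14757125 to 14757241, signal 446.7). Its ranks were 4220, 361 and 1799, so the replicates placed it far less evenly.

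The other 16 of the 20 strongest recurrent peaks were nearest to lncRNA:CR44619, CG14100, DNAlig3, Gapdh2, lncRNA:CR31840, px, CG32772, CenG1A, PNPase, Tina-1, jp, Chro, mRpL41, Art3, CG1635 and Lk6. Gapdh2 encodes a glycolytic enzyme, and its peak (X, 15867781 to 15868190, signal 2356) lay 180 bp upstream of the TSS in intergenic sequence. Chro encodes a chromodomain protein of chromatin domain borders and of the spindle, and its peak (3L, 22878722 to 22879075, signal 2092) lay in the 5′ UTR, 89 bp downstream of a TSS. The peak of mRpL41, a mitochondrial ribosomal protein gene (2R, 15217564 to 15217926, signal 2070), lay 141 bp upstream. Signal over the 20 ran from 2052 to 3724. Of the 20 summits, 12 were within 500 bp of a TSS and 14 were on the upstream side of the nearest one.

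BtbVII itself carried a strong peak in an intron, 105 bp from a TSS (3L, 3149059 to 3149439). Its signal of 1771 ranked 37 in the pooled list, and 37, 49 and 17 in replicates 1, 2 and 3. The fly line carries a tagged BtbVII gene, and the number of copies of this region in it is not given in the sources used here. No strong peak lay within 1000 bp of a TSS of psq, another BTB gene whose protein binds GA-rich DNA; its best candidate had a signal of 111.8, against a minimum of 172.4 for strong peaks. None of the 8 Hox genes had a strong peak within 1000 bp of a TSS. Dfd had a candidate at 170.4, Antp at 104.3, abd-A at 70.0, Ubx at 64.7 and Abd-B at 56.1, while lab, pb and Scr had no candidate summit within 1000 bp of a TSS.

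The replicates shared most of their high-ranking regions. The strong peaks come from the list pooled over these same replicates, so part of the support below is built in. Replicate 1 supported 4399 of the 5219 strong peaks (84.3%, 95% interval 83.3 to 85.3), replicate 2 supported 4393 (84.2%, 83.2 to 85.2) and replicate 3 supported 3951 (75.7%, 74.5 to 76.9). All 3 replicates supported 3076 peaks (58.9%, 57.6 to 60.3), exactly 2 supported 1421, 1 supported 673 and none supported 49. Support was complete for 95.6% of peaks in the top decile of signal, 79.9% in the fifth decile and 4.99% in the lowest. Each replicate was limited to as many regions as the list holds, so a peak near its lower end fell outside by a small difference in rank, and part of this fall follows from that limit. When any of the 30000 candidate regions counted, 4972 peaks (95.3%) lay in a region of every replicate.

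**Figure D1:**
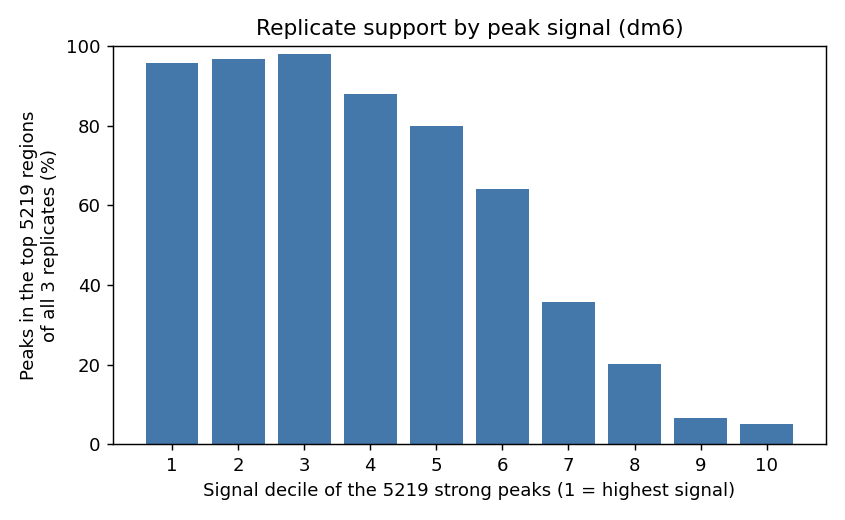
Share of strong peaks (percent, y axis) whose summit lay in the 5219 top regions of all 3 replicates, for each signal decile of the strong peaks (x axis, 1 is the highest signal). Bars rise from 95.6% in decile 1 to 97.9% in decile 3 and then fall to 4.99% in decile 10, in part because each replicate was limited to 5219 regions.

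Between replicates, 76.0% of the top 5219 regions overlapped for 1 and 2, 72.1% for 1 and 3 and 71.4% for 2 and 3, a mean of 73.2% ± 2.49 (SD over the 3 pairs). Random placement gave means of 3.04% to 3.10% and at most 3.67% in 100 draws. Across shared candidate regions, Spearman's rho of signal was 0.646 for 1 and 2 (17780 regions), 0.617 for 1 and 3 (16398 regions) and 0.615 for 2 and 3 (15744 regions). These correlations are across regions, which are not independent, and the 3 pairs share libraries, so no test was made between pairs.

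Strong peaks lay at promoters more often than weaker candidates did, and more of their promoter summits were upstream of the start site. Of the 5219 summits, 2578 (49.4%, 48.0 to 50.8) were within 500 bp of a TSS, against 5490 of the 21880 weaker candidates (25.1%, 24.5 to 25.7; odds ratio 2.91, Fisher's exact test, adjusted p = 7.84e-244). Random placement within chromosomes gave 13.6% on average and at most 14.6% in 100 draws. Among promoter-proximal summits, 68.3% (66.5 to 70.1) of strong peaks were upstream of the nearest TSS against 55.3% (54.0 to 56.6) of weaker candidates (Fisher's exact p = 3.63e-29), with median positions of −86.5 bp and −25 bp relative to the TSS. Coding exons held 20 strong summits outside promoters (0.383%) against 2.65% of weaker candidates (adjusted Fisher p = 7.11e-32), and 3′ UTRs held 1.13% against 2.78% (adjusted p = 1.05e-13). Introns held 37.0% against 47.0% (adjusted Fisher p = 2.62e-39) and intergenic sequence 10.4% against 20.8% (adjusted p = 1.12e-72). All these shares are over all summits, so a higher promoter share by itself lowers the others. Of summits outside promoters, introns held 1929 of 2641 strong and 10285 of 16390 weaker ones, a larger share of the strong ones. Intergenic sequence held 545 and 4542 of them, still a smaller share of the strong ones. These shares outside promoters were not tested. The shares in 5′ UTRs (0.632% and 0.878%, adjusted Fisher p = 0.104) and non-coding exons (1.05% and 0.836%, adjusted p = 0.137) did not pass the test.

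The promoter share fell with signal down the pooled list, from 52.8% of regions ranked 1 to 2500 to 18.3% of those ranked 25001 to 27500. It was level at the end, with 18.4% at ranks 27501 to 30000. GC content within 100 bp of the summit moved the other way, from 36.7% ± 8.0 (SD over 2500 regions) to 41.6% ± 8.0. It averaged 37.7% ± 8.16 over strong peaks and 40.6% ± 8.15 over weaker candidates, and the gap was present near TSSs (38.7% and 41.8%) and away from them (36.8% and 40.2%).

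**Figure D2:**
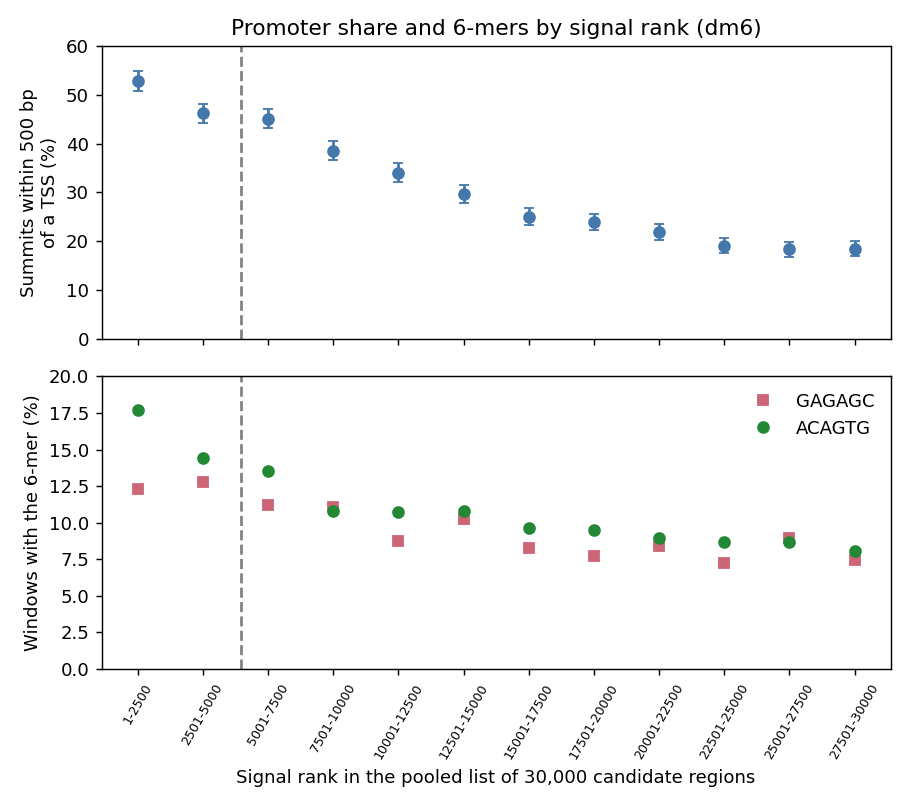
Top panel: summits within 500 bp of a TSS (percent, y axis; bars are exact 95% intervals) in bins of 2500 regions by signal rank in the pooled list (x axis). Bottom panel: windows of 100 bp on each side of the summit that hold GAGAGC or ACAGTG (percent). The dashed line marks the last strong peak, rank 5219. The promoter share falls from 52.8% to 18.4%, ACAGTG from 17.7% to 8.04% and GAGAGC from 12.3% to 7.48% between the first and the last bin.

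The X chromosome held 844 of the 5203 strong peaks on X and the major autosome arms (16.2%, 15.2 to 17.3), against 17.1% (16.6 to 17.6) of weaker candidates. The Fisher's exact p was 0.123, and the difference did not pass the threshold. Set against the share of X in chromosome length, 17.8%, the 16.2% was lower (exact binomial p = 0.00349).

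Of the 23 gene lists tested, ribosomal protein genes had the highest share near strong peaks. Of 86 with a candidate region, 71 (82.6%, 72.9 to 89.9) had a strong peak within 1000 bp of a TSS, against 41.6% of the other genes (odds ratio 6.64, Fisher's exact test, adjusted p = 2.80e-13), and the 71 genes had 71 distinct peaks. The summits lay close to the TSS, at a median distance of 26 bp, with a median signal of 496.9. The strongest were at RpS27 (3R, 25247335 to 25247694, signal 1386, 5′ UTR, 16 bp from the TSS), RpL7 (2L, 10200885 to 10201196, signal 1206, 5′ UTR) and RpL24 (2L, 13394978 to 13395269, signal 967.3, 5′ UTR). The mitochondrial ribosomal protein genes, which serve a separate ribosome, were near a strong peak in 24 of 48 cases (50%, adjusted Fisher p = 0.557), and proteasome genes in 6 of 18 (33.3%, adjusted p = 0.658).

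Genes of the EGFR and FGF signalling pathways were also more often near strong peaks, at 13 of 17 (76.5%, 50.1 to 93.2) against 42% of other genes (odds ratio 4.49, adjusted Fisher p = 0.0421). The strongest peaks were at Raf, the MAP kinase kinase kinase of the pathway (X, 2296143 to 2296326, signal 814.9, 5′ UTR), spi, an EGFR ligand (2L, 19575623 to 19575936, signal 771.7, intron), aos, a secreted inhibitor of EGFR (3L, 16483670 to 16484119, signal 608.4, in an intron of the overlapping gene CG33158), and sty, an intracellular inhibitor (3L, 3418436 to 3418599, signal 396.0, intron). This call was lost under 7 of 10 alternatives. The odds ratio stayed at 4.30 with a 2000 bp window (adjusted Fisher p = 0.0562). It fell to 2.07 with a 500 bp window (adjusted Fisher p = 0.497) and 2.59 with one TSS per gene (adjusted p = 0.317). Among sets with fewer peaks it was 2.71 without replicate 1 (adjusted Fisher p = 0.328), 2.74 without replicate 2 (adjusted p = 0.259), 3.11 for peaks supported in all 3 replicates (adjusted p = 0.138) and 1.67 for the higher-signal 2609 (adjusted p = 0.773). Without replicate 3 it was 5.13 and the call was kept (12 of 17, adjusted Fisher p = 0.00936). Over the 10 alternatives the adjusted p ran from 1.14e-04 to 0.773.

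Cuticle protein genes, which build the exoskeleton, were less often near strong peaks, at 3 of 28 (10.7%, 2.27 to 28.2) against 42.2% (odds ratio 0.164, adjusted Fisher p = 0.00485). The 3 were Cpr73D (3L, 16956627 to 16957076, signal 275.7), whose summit also lay in an intron of Ogdh, Cpr65Av (3L, 6140113 to 6140562, signal 177.6, intergenic) and Cpr67Fb (3L, 10893330 to 10893779, signal 173.9, intergenic). The call was lost in 2 sets that hold fewer peaks, those supported without replicate 2 (odds ratio 0.186, adjusted Fisher p = 0.122) and the higher-signal 2609 (odds ratio 0.113, adjusted p = 0.0789); over 10 alternatives the adjusted p ran from 4.86e-09 to 0.122.

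The other 20 lists did not pass Fisher's exact test. The share of all 7413 background genes near a strong peak was 42.1%. Of 11 heat shock genes, 8 were near a strong peak (adjusted Fisher p = 0.286), with signals of 1927 at the chaperone gene Hsp83, 996.9 at Hsp27 and 665.9 at stv. This list passed for peaks supported without replicate 3 (adjusted Fisher p = 0.0379, over 10 alternatives 0.0379 to 0.497). Of 14 BTB transcription factor genes, 9 were near one (adjusted Fisher p = 0.310), including Cp190 at 1068 and lola at 535.4 beside BtbVII. This list passed when summits in gene bodies counted (15 of 17, 88.2%, adjusted Fisher p = 0.00592) and with all protein-coding genes as background (50%, adjusted p = 0.0253), and over 10 alternatives the adjusted p ran up to 0.963. When gene bodies count, a longer gene can hold more summits, and length was not adjusted for here or in the lists below. Of 12 Dpp pathway genes, 8 were near one (adjusted Fisher p = 0.358), including the transcription factor genes shn at 1378 and brk at 680.7. They passed with all protein-coding genes as background (53.3%, adjusted Fisher p = 0.0253, over 10 alternatives 0.0253 to 1). Insulator protein genes (6 of 10, adjusted Fisher p = 0.557) included Chro. Trithorax group genes (9 of 16, adjusted Fisher p = 0.557) included the remodelling ATPase gene brm at 848.3, and they passed with gene bodies (17 of 20, 85%, adjusted p = 0.00592, over 10 alternatives 0.00592 to 1). Polycomb group genes (7 of 14, adjusted Fisher p = 0.720) included the neighbouring genes ph-p at 1871 and ph-d at 1197. Ecdysone response genes (6 of 12, adjusted Fisher p = 0.720) included the nuclear receptor gene Eip75B at 890.4. The gut, fat body and trachea regulators (8 of 14, adjusted Fisher p = 0.557) included fkh at 1003 and trh at 890.1, and passed with all protein-coding genes as background (53.3%, adjusted p = 0.0253, over 10 alternatives 0.0253 to 0.917). Segment polarity genes were near a strong peak in 4 of 8 cases (adjusted Fisher p = 0.837), Notch pathway genes in 7 of 16 and seminal fluid and testis genes in 5 of 11 (adjusted Fisher p = 1 for both). With all protein-coding genes as background, which adds genes without a candidate region, the seminal fluid and testis genes were below other genes (5 of 69, 7.25% against 22.4%, adjusted Fisher p = 0.00528).

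The remaining 7 lists had shares below 42.1%. None of 5 Hox genes with a candidate was near a strong peak (adjusted Fisher p = 0.287), and 0 of 5 allows a share of up to 52.2%. With gene bodies counted, 3 of 7 Hox genes had a strong peak (42.9% against 47.2% of other genes, adjusted Fisher p = 1, over 9 alternatives 0.104 to 1). Of 13 neurogenesis genes, 2 were near one (adjusted Fisher p = 0.287), among them the neuronal RNA-binding protein gene elav at 1471. Of 9 gap and pair-rule genes, 2 were near one (adjusted Fisher p = 0.557), among them hb at 485.7. Germline genes (2 of 8) and muscle and mesoderm genes (6 of 18, including tin at 438.4) each had an adjusted Fisher p of 0.658. Cell cycle genes were near one in 5 of 14 cases (adjusted Fisher p = 0.864), including CycE at 574.8. Chemoreceptor genes were near one in 6 of 29 cases, with a Fisher p of 0.0226 that adjustment raised to 0.130. Their share was lower past the threshold with gene bodies (24.4%, adjusted Fisher p = 0.0161) and with all protein-coding genes as background (3.35%, adjusted p = 7.34e-12), and over 10 alternatives the adjusted p ran up to 0.853. The replication-dependent histone genes (0 of 111 with a candidate region) and the eggshell and yolk genes (1 with a candidate, Cp190) were too few to test. With all protein-coding genes as background both could be tested. The histone genes were then lower (0 of 111 against 22.5%, adjusted Fisher p = 7.34e-12), and the eggshell and yolk genes did not pass (adjusted p = 0.122). The histone genes are repeated in tandem copies, and how reads in repeats were treated is not given in the sources used here. Most lists are short and their intervals wide, so a p that misses the threshold does not show that a list was near strong peaks as often as other genes.

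**Figure D3:**
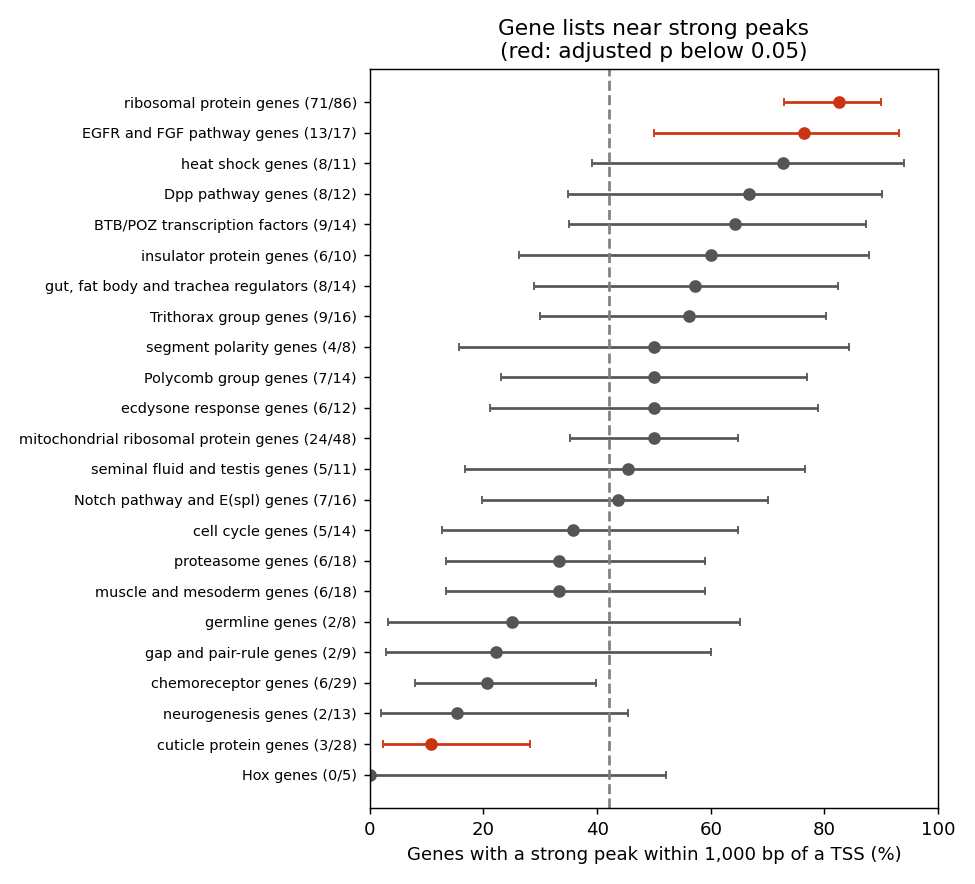
Share of the genes in each of 23 lists (percent, x axis) with a strong peak within 1000 bp of a TSS; labels give genes near a strong peak over genes with a candidate region. Points are shares, bars exact 95% intervals, the dashed line is the share of all background genes (42.1%), and red marks the 3 lists with an adjusted p below 0.05.

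Alternating GA sequence of the GAGA type was more frequent at strong peaks than at matched weaker candidates. The GAGA repeat (GAGAGA) was in 13.5% of 5214 strong windows (12.6 to 14.5) against 8.88% of matched windows (8.12 to 9.68; odds ratio 1.61, adjusted Fisher p = 8.28e-13). It passed in all of 100 other draws of the matched windows (odds ratios 1.41 to 1.75). Its odds ratio was 1.28 within 50 bp of the summit (adjusted Fisher p = 0.0243) and 1.74 within 250 bp (adjusted p = 1.96e-33). The Tramtrack site was in 2.13% against 3.09% (odds ratio 0.683, adjusted Fisher p = 0.0216), a call that was lost in 5 sets with fewer peaks (adjusted p over 8 alternatives from 1.49e-08 to 0.196). The Tramtrack call was made in 62 of the 100 other draws (odds ratios 0.595 to 0.8). The odds ratio was 0.664 for the higher-signal 2609 peaks, 0.719 for those supported in all 3 replicates, and 0.721, 0.727 and 0.700 without replicate 1, 2 and 3. The other 15 motifs did not pass, although in the other draws the A tract passed in 33, the Zeste site in 27, the CTCF core in 21 and DRE in 2. Odds ratios were 1.06 for the site of Zelda, an activator of the zygotic genome, 0.804 for DRE, a core promoter element (adjusted Fisher p = 0.0785), 1.11 for Motif 1, 1.12 for the E-box, 0.918 for the Su(Hw) core, 0.978 for the Pho site, 1.1 for the Zeste site (adjusted p = 0.0867), 1.01 for the TATA box, 1.26 for the AP-1 site, 1.15 for the GATA site, 0.938 for the homeobox core, 1.04 for the CA repeat, 0.876 for the A tract (adjusted p = 0.0785) and 0.863 for the CAG repeat. The core site of the insulator protein CTCF was in 1.07% of strong and 0.767% of matched windows (odds ratio 1.40, adjusted Fisher p = 0.310), and it passed within 50 bp of the summit (odds ratio 3.91, adjusted p = 0.00175), within 250 bp (1.57, adjusted p = 0.0123) and without matching (1.45, adjusted p = 0.0403), with an adjusted p of up to 1 over 8 alternatives. Within 250 bp the Zeste site (odds ratio 1.17, adjusted Fisher p = 3.13e-04, over 8 alternatives up to 0.665) and the CA repeat (1.22, adjusted p = 0.00146, up to 1) also passed. The A tract passed within 50 bp (odds ratio 0.771, adjusted Fisher p = 0.00475) and for the higher-signal 2609 peaks (0.791, adjusted p = 0.0211), with up to 0.738 over 8 alternatives. Without matching, Motif 1 (odds ratio 1.75, adjusted Fisher p = 0.00118, over 8 alternatives up to 0.973), the TATA box (1.34, adjusted p = 6.05e-17, up to 0.976) and the CAG repeat (0.631, adjusted p = 3.14e-05, up to 0.896) passed, and DRE (1.30, adjusted p = 0.00269, up to 0.384), the homeobox core (1.12, adjusted p = 0.0403, up to 1) and the CA repeat (0.856, adjusted p = 0.0403) passed in the opposite direction.

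Of 2080 6-mers, 98 were more frequent and 97 less frequent at strong summits. The lowest p-values belonged to ACAGTG (16% against 9.61%, odds ratio 1.79, adjusted Fisher p = 1.99e-19) and GAGAGC (12.5% against 6.90%, odds ratio 1.93, adjusted p = 1.99e-19). Over 100 other draws of the matched windows the odds ratio ran from 1.58 to 1.93 for ACAGTG (median 1.76) and from 1.49 to 1.86 for GAGAGC (median 1.69), so the reported 1.93 for GAGAGC lay above all of them. AGAGCG (11.6% against 6.79%), AGAGAG (14.5% against 9.30%) and GAGAGA (13.5% against 8.88%) followed and overlap GAGAGC in sequence. Less frequent were CCAGGA (1.99% against 4.35%, adjusted Fisher p = 1.64e-09), CAGGAC (1.44% against 3.07%), CGAGGA (2.57% against 4.55%), GAGGAC (1.38% against 2.90%) and GAAGGA (3.78% against 5.93%). For the higher-signal 2609 peaks the calls of CGAGGA (odds ratio 0.657 against 0.554, adjusted Fisher p = 0.110, over 6 alternatives 2.56e-15 to 0.110) and GAAGGA (0.703 against 0.623, adjusted p = 0.117, over 6 alternatives 1.45e-14 to 0.117) were lost. Neighbouring 6-mers share sites, so the 195 do not represent as many separate sequences, and 125 passed for peaks supported without replicate 1. In 20 other draws of the matched windows 139 to 197 passed, with 107 to 130 shared with the 195.

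**Figure D4:**
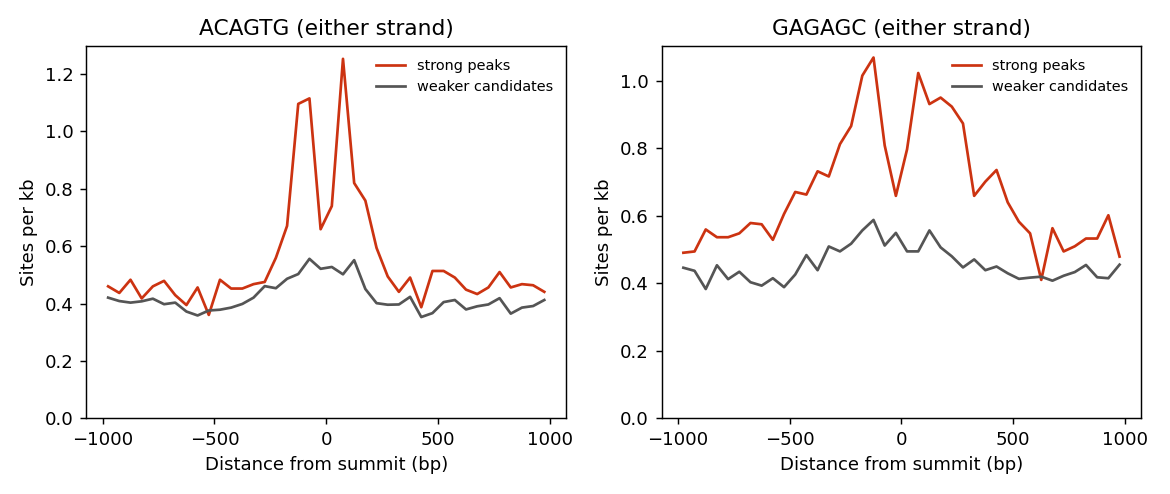
Sites of ACAGTG (left) and GAGAGC (right) per kb of sequence (y axis), in 50 bp steps by distance from the summit (x axis, bp), over 5219 strong peaks (red) and 21880 weaker candidates (grey). At strong peaks ACAGTG reaches 1.25 sites per kb at 75 bp from the summit and GAGAGC 1.07 at −125 bp, and both are lower at the summit itself.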

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

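The single-TSS setting was chosen after the data were seen; all other settings were planned. The promoter share stayed above its background in all 9 alternatives (33.5% to 60.2%), ribosomal protein genes stayed past the threshold in all 10 (76.7% to 84.1% near a peak), and so did the GAGA repeat (8 alternatives), ACAGTG and GAGAGC (6 each). Among its 8 alternatives, the odds ratio of the GAGA repeat was lowest within 50 bp of the summit, at 1.28. Taking the upper part of the signal ranking leaves 2609 peaks by construction. Support in all 3 replicates fell to 1684 peaks when the top N/2 regions were used (N = 5219), by construction. The mean overlap of replicate pairs was 70.4% with the top 2N regions, 69.9% with a summit in the other's region and 64.4% with 50% reciprocal overlap; leaving out a replicate gave 71.4% to 76.0%. The X share was the same 16.2% with chromosome length as background, where it passed the threshold.

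The number of gene lists past the threshold, 3, became 1 with the 2609 peaks, 1 to 4 without a replicate, 6 with gene bodies and 9 with all protein-coding genes as background, where all 25 lists were tested. For motifs, 2 became 1 with peaks supported in all 3 replicates, 1 in each case without a replicate, 4 with 50 bp, 5 with 250 bp and 9 without matching. For 6-mers, 195 became 105 with the 2609 peaks (82 shared), 125 with peaks supported in all 3 replicates (102 shared), 125 to 139 without a replicate (106 to 118 shared) and 1096 without matching (169 shared). Without matching, motifs and 6-mers were tested against all 21880 background windows and not 5214, which can lower p at an equal odds ratio. For ACAGTG the odds ratio was 1.79 with matching and 1.80 without, while the adjusted Fisher p went from 1.99e-19 to 4.60e-35. Sets without a replicate are strong peaks supported in both others; they hold fewer peaks, and IDR itself could not be run again, so the peak count has no such value. Direction reversed for seminal fluid and testis genes with all protein-coding genes as background (7.25%, below other genes). That setting keeps the same genes near a strong peak and adds genes without a candidate region. Of seminal fluid and testis genes, 5 were near a strong peak in both settings, of 11 and of 69 counted. Their reversal therefore follows from the added genes. Without matching, direction reversed for DRE (odds ratio 1.30), the homeobox core (1.12) and the CA repeat (0.856). Matching changed base composition, promoter share and the number of background windows together, and which of them moved these values was not tested. For the other changes, except counts that fall by construction and gene lists set against all protein-coding genes, the cause was not tested. Odds ratios also moved in sets with fewer peaks, so a lost call need not come from their number. With the 2609 peaks the odds ratio fell from 4.49 to 1.67 for EGFR and FGF pathway genes and rose from 6.64 to 10.5 for ribosomal protein genes. Of the single lists, motifs and 6-mers, 387 alternatives kept direction and side of the threshold, 18 passed it newly, 16 lost it and 4 reversed; the 387 include 52 changes of sign, past the threshold in neither setting, that were not called reversals. On dm3 there were 4373 peaks, 2618 of them supported in all 3 replicates. No paired analysis was possible because there is one group. Depth is unknown, so which of the peaks near the lower end of the ranking would pass with deeper libraries cannot be told from these lists.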

Other observations

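The gene lists and RNA classes in this part, and the tests of housekeeping genes, base composition and distance from the summit, were chosen only after the results they bear on were seen; the tests of abundant transcripts, of simple GA repeats and of an extra gene copy were written before their values were computed. None of these lists was run under the alternative settings.

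Of 11 added lists, abundant transcripts outside the ribosome stood out: 30 of 36 genes (83.3%, 67.2 to 93.6) had a strong peak within 1000 bp, against 41.9% of other genes (Fisher's exact test, Benjamini-Hochberg adjusted p = 5.46e-06). They include the glycolytic enzyme gene Eno (signal 1154), the elongation factor gene eEF1gamma (1044), the ferritin genes Fer1HCH and Fer2LCH (771.6, 1 shared peak), alphaTub84B (653.9) and Act5C (554.3). The list was drawn up from general knowledge, not from expression measured in these embryos, and left out Gapdh2 and Hsp83, whose peaks had been seen. Translation factor genes (22 of 34, 64.7%, adjusted Fisher p = 0.0235; eIF6 1327) and septate junction and adhesion genes (9 of 11, 81.8%, adjusted p = 0.0235; dlg1 367.9) were also more often near strong peaks. Less often near them were oxidative phosphorylation genes (11 of 48, 22.9%), cytochrome P450 genes (8 of 39, 20.5%) and trypsin and Jonah protease genes (0 of 9), each with an adjusted p of 0.0235. Apoptosis genes (5 of 8, adjusted Fisher p = 0.404), V-ATPase genes (7 of 13, adjusted p = 0.503), chaperonin genes (3 of 6, adjusted p = 0.771), circadian clock genes (3 of 7, adjusted p = 1) and odorant binding protein genes (2 of 11, adjusted p = 0.210) did not pass.

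Among RNA classes, tRNA genes (58 of 219, 26.5%, adjusted Fisher p = 5.42e-06) and long or other non-coding RNA genes (413 of 1337, 30.9%, adjusted p = 3.88e-14) were near strong peaks less often than protein-coding genes (42.1%), while snoRNA genes (61 of 130, 46.9%, adjusted p = 0.377) and snRNA genes (4 of 14, adjusted p = 0.419) did not pass the test.

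The first pattern weighed is the excess of ribosomal protein genes (82.6%). Mitochondrial ribosomal protein and proteasome genes together reached 45.5% (30 of 66), below ribosomal protein genes (Fisher's exact p = 2.09e-06). Their shares were known when this test was chosen, so it cannot decide on housekeeping promoters as a class, which stay open. Other lists of broadly needed genes were mixed. Translation factor genes reached 64.7%, V-ATPase genes 53.8%, chaperonin genes 50% and oxidative phosphorylation genes 22.9%. Strong signal at abundantly transcribed promoters, whatever protein is tagged, stays open: abundant transcripts outside the ribosome reached 83.3%, above other genes (Fisher p = 4.12e-07) and not separable from ribosomal protein genes (p = 1). A candidate explanation is therefore the general openness or activity of such promoters, and an immunoprecipitation of another GFP protein or of GFP alone, not used here, would be needed to tell. No biological explanation was tested, since there is one group.

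The second pattern is the excess of GAGAGC and ACAGTG at strong summits, sequences picked and tested on the same data. The matched excess of both sequences was known when the tests of GC content and promoter share were chosen, so their outcome was largely set beforehand. They show only that an excess remained at an equal GC bin and promoter class. Over 100 other draws of matched windows the odds ratio of GAGAGC was at least 1.49 (1.55 without matching, highest Fisher p = 9.38e-07 after Bonferroni adjustment over 2080 6-mers). ACAGTG ranked 1 when 6-mers were picked on chromosome 2 and had an odds ratio of 1.56 on the other chromosomes (Fisher's exact p = 1.86e-09). GAGAGC ranked 11 there, outside the 5 counted as picked (odds ratio 1.73 on the other chromosomes). With partners drawn over the genome and not matched within each part, GAGAGC ranked 3, inside the 5 (odds ratio 2.05). Those partners are the reported draw, whose odds ratio of 1.93 for GAGAGC lay above all 100 others, so the pick on chromosome 2 does not settle GAGAGC. GA runs of at least 8 bp as the whole cause are argued against, since without windows that hold them GAGAGC kept an odds ratio of 1.77 (10.4% against 6.15%). Over the 100 other draws it was 1.37 to 1.74 (highest adjusted Fisher p = 0.0136), so the reported 1.77 lay above all of them. Shorter or imperfect GA repeats were left in, so they stay open. ACAGTG was 2.08 times (bootstrap 95% interval 1.91 to 2.25) as dense within 100 bp of strong summits as at 500 to 900 bp. At weaker candidates its ratio was 1.34. Both sequences were picked for their frequency within those same 100 bp, which favours a high ratio. At 500 to 900 bp, outside the window of the pick, ACAGTG had 0.453 sites per kb at strong peaks and 0.393 at weaker candidates. The ratio therefore does not decide on a spread of sites over open chromatin around the peaks, which stays open for ACAGTG. Such a spread stays open for GAGAGC too. Its ratio of 1.52 (1.38 to 1.66, and 1.23 at weaker candidates) was above the limit of 1.5 by less than its spread. That either sequence may mark sites where BtbVII or a partner contacts DNA is a hypothesis only, and other proteins that bind GA-rich DNA, GAGA factor among them, stay open since no profile of them was used here.

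The third pattern is the strong peak at BtbVII itself. An extra copy of the region in the tagged line could raise the surroundings too. Within 20 kb of the gene lay 14 other candidate regions, against a median of 11 for 2739 protein-coding genes on 3L, the 62.0th percentile. By strong peaks alone, 5 others lay there, the 82.6th percentile. A count of regions need not follow a gain of signal, and a control from the same line would hold the same extra copy. The counts therefore do not decide on a broad gain, and a gain of a short segment around the promoter stays open too. Binding of BtbVII to its own gene was not tested against any other line.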
